A study of Mus musculus with 10 samples.

How the data were processed

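Liver RNA of female mice of the inbred strains B6 (C57BL/6J) and D2 (DBA/2J) was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array for each strain at 0, 1, 4, 12 and 21 weeks on a diet high in fat and cholesterol. Per the labels, total RNA was extracted with Trizol and each array holds a pool of 5 mice. The deposited values are signal intensities on a linear scale that the authors computed with the GCOS software, for which the labels give no version. Of 45101 probe sets, 64 control probe sets were left out of the tests. The 2% trimmed means of the arrays ranged from 56.2 to 89.1, a ratio of 1.59, and the geometric mean of 9 spiked control probe sets varied by a ratio of 1.35. Because the trimmed means differed by more than 1.5 times, the arrays were quantile normalised in limma, by a rule written before the data were examined, together with the comparisons, gene lists, named genes and alternatives described here.

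Values were analysed as log2(signal + 1.05), the pseudocount being the 10th percentile of all deposited values. Probe sets with a single gene symbol (34945) were used, 932 with several symbols and 9160 without one were not, and symbols were updated through their gene identifiers from RefSeq annotation. The named probe sets covered 18193 genes. Each gene was represented by its probe set with the highest mean, and genes were kept where that mean lay above the 50th percentile of all probe sets' means, 3.74 on the log2 scale, which left 11062 genes.

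Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with trend), with the packages statmod 1.5.0 and data.table (version 1.17.8), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. The strain comparison (D2 minus B6) had week as a block, since the labels pair 1 B6 and 1 D2 pool at each week, and left 4 residual degrees of freedom. The diet comparison set the 8 fed arrays against the 2 week 0 arrays with strain as a term (7 degrees of freedom). The response within each strain and its difference between the strains came from 4 group means (6 degrees of freedom), and the trend was a slope on log2(week) over the 8 fed arrays with strain as a term (5 degrees of freedom). The weeks served as replicates, so the spread includes time on the diet. A lone week 0 array was assumed to vary like the fed arrays.

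Gene lists for liver lipid metabolism, cell types and other processes were written in advance from textbook knowledge. Of 28 lists, 25 with at least 5 genes kept were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the arrays, and with fry. Of 538 list entries, 50 had no named probe set. Named genes were the 10 largest rises and falls among genes that passed and moved the same way in every week or fed array, up to 4 members of each list, and a fixed set of lipid, inflammation and strain genes. Not every gene that this rule allows is printed.

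The fits were tested on simulated data with 100 genes changed by 1 or 2 on the log2 scale. At 1, the strain fit recovered 64%, the diet fit 60%, the fits within B6 and D2 33% and 31%, the interaction 12% and the trend 40%. At 2, these were 95%, 87%, 76%, 77%, 58% and 83%. A simulated list of 20 genes shifted by 1 was called by camera in all fits except the interaction, and with an estimated correlation only in the strain, diet and D2 fits. Between 3 and 14 unchanged genes were called per fit, and camera at the preset correlation also called 1 unshifted list in the trend fit. The simulated genes varied independently of each other. The simulation therefore does not show how often camera calls unshifted lists whose genes vary together.

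Alternatives were another pseudocount, a floor instead of a pseudocount, median centring, other filters, other ways to choose or combine probe sets, other variance models, other forms of the design, and each array left out in turn. Values as deposited, values centred on the tested genes and 2 further pairs of left-out arrays were added after seeing the data.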

Results

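Liver transcripts were measured in female mice of 2 inbred strains, C57BL/6J (B6) and DBA/2J (D2), before and during feeding with a diet rich in fat and cholesterol. Livers were taken at 0, 1, 4, 12 and 21 weeks on the diet. RNA of 5 mice was pooled for each strain and week, and each pool was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, so the series held 10 arrays, 5 per strain. Each strain had 1 array before the diet and 4 fed arrays, and age increased together with the weeks on the diet. The 2% trimmed mean signal ranged from 56.2 to 89.1 over the arrays and was lowest in both week 0 arrays. Correlations between arrays of a strain ranged from 0.911 to 0.967 in B6 and from 0.957 to 0.982 in D2. Values below are log2 normalised signals, changes are on the log2(signal + pseudocount) scale, and the number of arrays limits their precision.

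The first comparison asked which transcripts differed between the strains over all weeks. Among the largest differences towards D2 was that of Sult3a1, a sulfotransferase gene, which was higher in D2 by 6.66 ± 0.95 on the log2 scale (SE, 5 arrays per strain, adjusted p = 0.00526). Others were H2-Ea, an MHC class II chain whose promoter carries a deletion in C57BL/6J (5.68 ± 0.33, adjusted p = 6.49e-05), the cytochrome P450 gene Cyp2c39 (4.96 ± 0.14, adjusted p = 4.43e-06), Corin, a serine protease gene (4.93 ± 0.28), and Cap1, an actin-binding protein gene (4.41 ± 0.17). Among the largest differences the other way were those of Mndal, an interferon-inducible gene (−5.55 ± 0.43, adjusted p = 0.000317), Ildr2 (−4.96 ± 0.26, adjusted p = 5.87e-05), Nlrp12, a NOD-like receptor gene (−4.80 ± 0.35), Zfp874a, a zinc finger gene (−4.06 ± 0.28), and Pdxdc1, a decarboxylase-like gene (−3.60 ± 0.13), for which another probe set passed in the opposite direction. Each of these 10 genes differed the same way at all 5 weeks, which was a condition for naming it here. Signals near background, such as those of Sult3a1 at 0.79 and Corin at 1.72 in B6 at week 1, make the size and order of these differences uncertain, and Sult3a1 was at 9.67 in B6 at week 0. Mndal and Ildr2 were read by probe sets that can bind more than 1 transcript.

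In all, 883 of 11062 genes differed between the strains in limma with week as a block. Of these, 432 were higher and 451 lower in D2, and 306 differed by at least 2-fold. With the arrays left at the authors' own scale, 208 were higher and 403 lower. The 6 genes with known inherited differences between the strains all passed. Nnt, a mitochondrial transhydrogenase partly deleted in C57BL/6J, was at 8.87 ± 0.19 in B6 and 10.06 ± 0.09 in D2 (SD, n = 5 arrays each). Alad and Glo1, both duplicated in DBA/2J, were higher in D2 by 1.32 ± 0.11 and 0.80 ± 0.12 (SE). Lower in D2 were the complement gene Hc (−1.27 ± 0.07), the natural killer receptor gene Klrd1 (−1.63 ± 0.37) and Gpnmb (−3.62 ± 0.72), which are known loss-of-function loci of DBA/2J. Without 1 of the arrays the Gpnmb call was lost for either array of week 4, 12 or 21 (adjusted p up to 0.0817), and the Klrd1 call for any fed array (up to 0.133). The count of genes was 556 and 557 without the B6 or D2 week 4 array, 429 and 430 without those of week 12, and 390 and 386 without those of week 21. With week as a block, leaving out either array of a week takes both out of the strain difference. Each such pair of counts therefore comes from nearly the same fit.

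**Figure D1:**
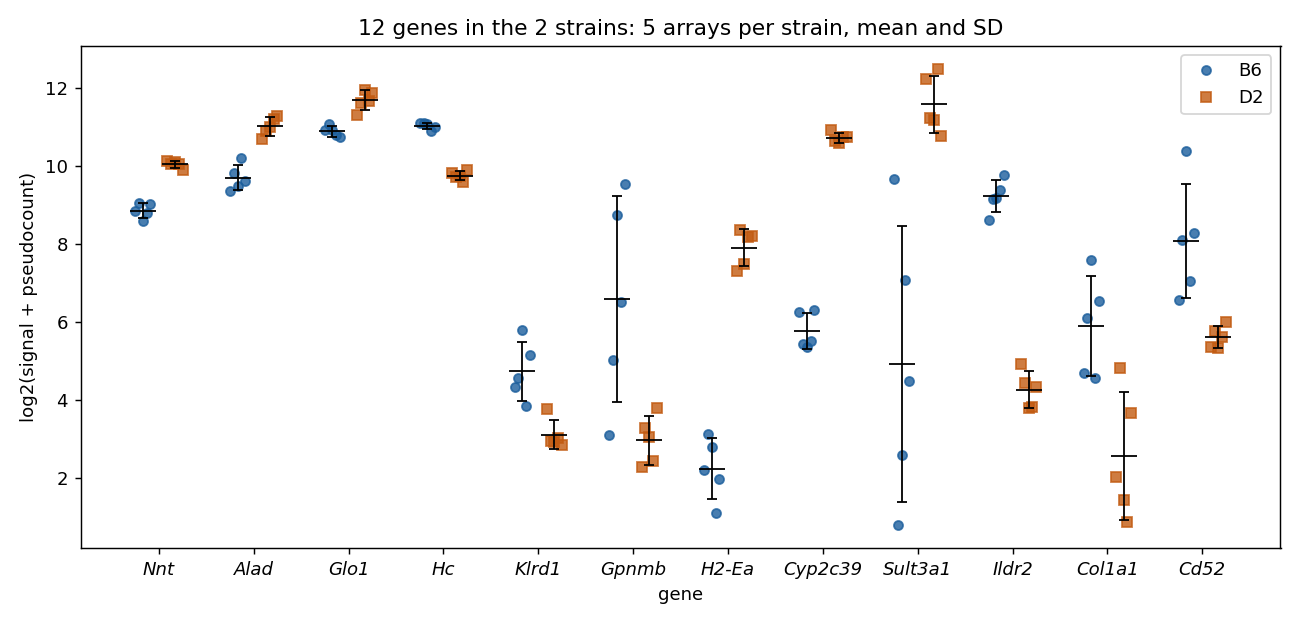
Normalised log2 signal of 12 genes (vertical axis, log2(signal + pseudocount)) in the 5 B6 arrays (circles) and 5 D2 arrays (squares), with the mean and SD in black. All 12 passed the test between the strains; Nnt averaged 8.87 in B6 and 10.06 in D2, and Sult3a1 was at 10.78 or above in every D2 array.

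Genes of fatty acid and bile acid handling differed in both directions. Of 21 fatty acid synthesis genes, 1 was higher and 3 were lower in D2, or 4 and 4 adjusted over the list alone. Lpin1, a phosphatidate phosphatase, was lower in D2 (−2.62 ± 0.30, adjusted p = 0.00201), and Acaca, the acetyl-CoA carboxylase of lipogenesis, differed by −0.93 ± 0.15 (adjusted p = 0.00882). Of 30 fatty acid oxidation and PPAR-alpha target genes, 3 were higher and 1 was lower, or 4 and 1 over the list alone. Fgf21, a hormone of the fasting liver, was higher in D2 by 2.32 ± 0.29 (adjusted p = 0.00307), while the fatty acid transporter gene Cd36 was lower (−1.31 ± 0.19, adjusted p = 0.0058). The median of this list was 0.16 (camera adjusted p = 0.0111, and adjusted p = 0.84 with an estimated correlation). Its call was lost without either array of week 1 or week 4 (adjusted p up to 0.353), and its median ranged from 0.03 to 0.28 with 1 array left out. Of 16 bile acid synthesis genes, 2 were higher, among them Cyp8b1, the sterol hydroxylase of cholic acid synthesis (2.96 ± 0.67, adjusted p = 0.035, lost without any 1 fed array, up to 0.107). The strains lay close in Cyp8b1 before the diet, so its difference came from the fed arrays. Of 13 bile and sterol transport genes, 5 were lower in D2, such as the canalicular transporters Abcc2 (−0.79 ± 0.08, adjusted p = 0.000947) and Abcg2 (−0.97 ± 0.15, adjusted p = 0.00865). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (1.64 ± 0.54, adjusted p = 0.108), nor did Scd1 (−0.41 ± 0.12, adjusted p = 0.0859), the sterol transporter gene Abcg8 (−0.32 ± 0.20, adjusted p = 0.372) or Sqle (0.86 ± 0.66, adjusted p = 0.469).

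Stellate cell and macrophage gene lists had negative medians in D2 against B6, while few of their genes passed. All 24 stellate cell and matrix genes had a negative difference, with a median of −0.68, and 5 passed the test, or 16 adjusted over the list alone (camera adjusted p = 1.53e-07, and adjusted p = 0.766 with an estimated correlation). Col1a1, the main fibrillar collagen chain, was at 5.90 ± 1.28 in B6 and 2.57 ± 1.64 in D2 (SD, n = 5 arrays each). All 25 macrophage and Kupffer cell markers were negative as well, with a median of −1.01, and 1 passed, Cd52 (−2.46 ± 0.49, adjusted p = 0.022). For this list the camera adjusted p was 8.18e-07, and the adjusted p was 0.84 with an estimated correlation. The macrophage median of D2 minus B6 was 0.08 at week 0, −0.61 at week 1, −3.03 at week 4, −0.05 at week 12 and −1.20 at week 21. The stellate median was −0.11 at week 0 and −0.34, −1.27, −0.70 and −0.92 at the later weeks. Lyve1, a hyaluronan receptor of endothelial cells, was lower in D2 (−1.74 ± 0.19, adjusted p = 0.00148), 1 of 2 among 15 endothelial markers that passed, while the median of that list was −0.05 (camera adjusted p = 0.214). Lymphocyte markers (median −0.39, camera adjusted p = 0.25) and blood cell markers (−0.21, camera adjusted p = 0.589) were not called. The median difference of 13 hepatocyte markers was −0.03, with 0 passing. Without B6 week 4, which takes the week 4 pair out of the strain difference, the macrophage median was −0.50 and 2 stellate genes passed. Without D2 week 12, and so without the week 12 pair, 0 stellate genes passed. Col1a1 was not called without either week 12 array (adjusted p up to 0.0604), nor Cd52 without either array of week 1 or 21 (up to 0.0696).

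Enzymes of detoxification and genes with sex-biased expression also differed. Of 19 NRF2 and glutathione genes, 5 were lower in D2 and 0 were higher, or 8 and 0 adjusted over the list alone, with a median of −0.42 (camera adjusted p = 3.89e-05, and adjusted p = 0.766 with an estimated correlation). The glutathione S-transferase gene Gsta2 differed by −1.84 ± 0.34 (adjusted p = 0.0165, lost without either array of week 1 or 12, up to 0.0694). Without the pair of week 1 (B6 array left out) or of week 12 (D2 array left out), 0 of the 19 passed. Without the pair of week 4 (B6 array left out) 1 passed. Cyp3a13 was lower (−1.95 ± 0.12, adjusted p = 0.00011) and Cyp2c38 higher (1.73 ± 0.19, adjusted p = 0.00182) among 23 drug-metabolising cytochrome P450 genes, of which 2 passed in each direction. Of 11 male-biased liver genes, 4 were higher in D2, or 7 over the list alone, with a median of 0.63 (camera adjusted p = 0.000782, and adjusted p = 0.766 with an estimated correlation). The elongase gene Elovl3 (1.74 ± 0.29) and the peroxisomal hydrolase gene Nudt7 (1.21 ± 0.19) were among them. Of 9 female-biased liver genes, 2 were higher, or 5 over the list alone, with a median of 0.41 (camera adjusted p = 0.00147, and adjusted p = 0.766 with an estimated correlation). These were Sult3a1 and the oxidase gene Hao2 (2.30 ± 0.26, adjusted p = 0.00184). The female-biased median was 1.36, 0.96, 1.45, 0.33 and 0.00 over the weeks, and from 0.30 to 0.95 with 1 array left out. The acute phase gene Apcs was higher in D2 (1.66 ± 0.12, adjusted p = 0.000217), as 1 of 4 among 25 acute phase genes.

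The calls of 2 further lists depended on the arrays of 1 week. The cell cycle list had a median of −0.40 over 17 genes, of which 1 was lower in D2, the ribonucleotide reductase gene Rrm2 (−2.54 ± 0.28, adjusted p = 0.0018), or 3 over the list alone (camera adjusted p = 0.00414, and adjusted p = 0.84 with an estimated correlation). The call was lost without either week 1 array (adjusted p = 0.263), with a median of −0.09 without B6 week 1. Cholesterol synthesis and uptake genes had a median of 0.57 over 20 genes, of which 1 was higher, Fdft1, and 1 lower, Sc5d (−1.34 ± 0.22), both enzymes of sterol synthesis. The Fdft1 call was kept only when the array left out was of week 1 (adjusted p up to 0.0937 otherwise). Over the list alone 2 were higher and 1 lower (camera adjusted p = 0.0144, and adjusted p = 0.84 with an estimated correlation). Without either week 12 array the cholesterol list lost its call, with a median of 0.16 (adjusted p = 0.633).

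The second comparison asked which transcripts differed between the fed arrays and the arrays before the diet in both strains. The clock output gene Dbp rose by 3.92 ± 0.42 (SE, adjusted p = 0.0139), from 5.58 to 9.09 ± 0.93 in B6 and from 5.97 to 10.30 ± 0.18 in D2 (SD, n = 4 fed arrays per strain). The clock genes Nr1d1 (2.80 ± 0.39) and Per3 (2.40 ± 0.35) rose as well, while Arntl, the activator of the core clock, fell (−2.46 ± 0.44, adjusted p = 0.0399). Other rises were in Mlkl, a gene of necroptosis (2.50 ± 0.41), the TNF receptor family gene Tnfrsf19 (2.42 ± 0.36) and the DNA polymerase subunit gene Pola2 (2.18 ± 0.37). Among genes that passed and moved the same way in all 8 fed arrays, falls were largest in Pdk4 and Cyp2b10. Pdk4, the kinase that restrains pyruvate oxidation in fasting, fell by −2.90 ± 0.46 (adjusted p = 0.0232), and the drug-metabolising gene Cyp2b10 by −2.75 ± 0.51 (adjusted p = 0.0427). The ammonium transporter gene Rhbg (−1.67 ± 0.23), the serotonin receptor gene Htr1b (−1.58 ± 0.27), Abtb2 (−1.52 ± 0.20), the vasopressin receptor gene Avpr1a (−1.45 ± 0.16) and Ccng2, a cyclin gene (−1.37 ± 0.18), also fell. Scd1, the main stearoyl-CoA desaturase of the liver, rose by 0.90 ± 0.14 (adjusted p = 0.0232). All of these genes moved the same way in all 8 fed arrays, which for all but Scd1 was a condition for being named. The changes of the 4 fed arrays of a strain also share its week 0 array.

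Of 11062 genes, 72 passed in limma with strain as a term, 46 rising and 26 falling, and 1931 had an unadjusted p under 0.05. Across all tested genes the changes of the strains correlated with Pearson's r = 0.375 and Spearman's rho = 0.345, with genes not being independent replicates, and 62.0% of genes had the same sign in both. The direction of many changes depended on the scale between arrays, since the median of all genes moved by 0.52 with the authors' own scale and by 0.16 with each array centred on its median. Then 4949 genes rose and 41 fell, or 276 rose and 37 fell, against 35 and 38 with arrays centred on the tested genes. Of the 21 genes that the naming rule picked among those that passed, 0 kept their call whichever array was left out, and the count was 14 without the B6 or without the D2 week 0 array, 47 without B6 week 21, 31 without D2 week 4 and 36 without D2 week 21. Dbp missed the threshold without the D2 week 0 array and Avpr1a without the B6 week 0 array. Without the week 0 array of a strain, its fed arrays no longer enter the change, which is then that of the other strain alone. Dbp and Avpr1a kept their calls without any 1 fed array, but other genes did not. Cyp2b10 also lost its call without B6 week 12 or 21 or D2 week 4, 12 or 21. Arntl also lost it without B6 week 21 or D2 week 1 or 4, and Pola2 without B6 week 1 or D2 week 4 or 21.

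**Figure D2:**
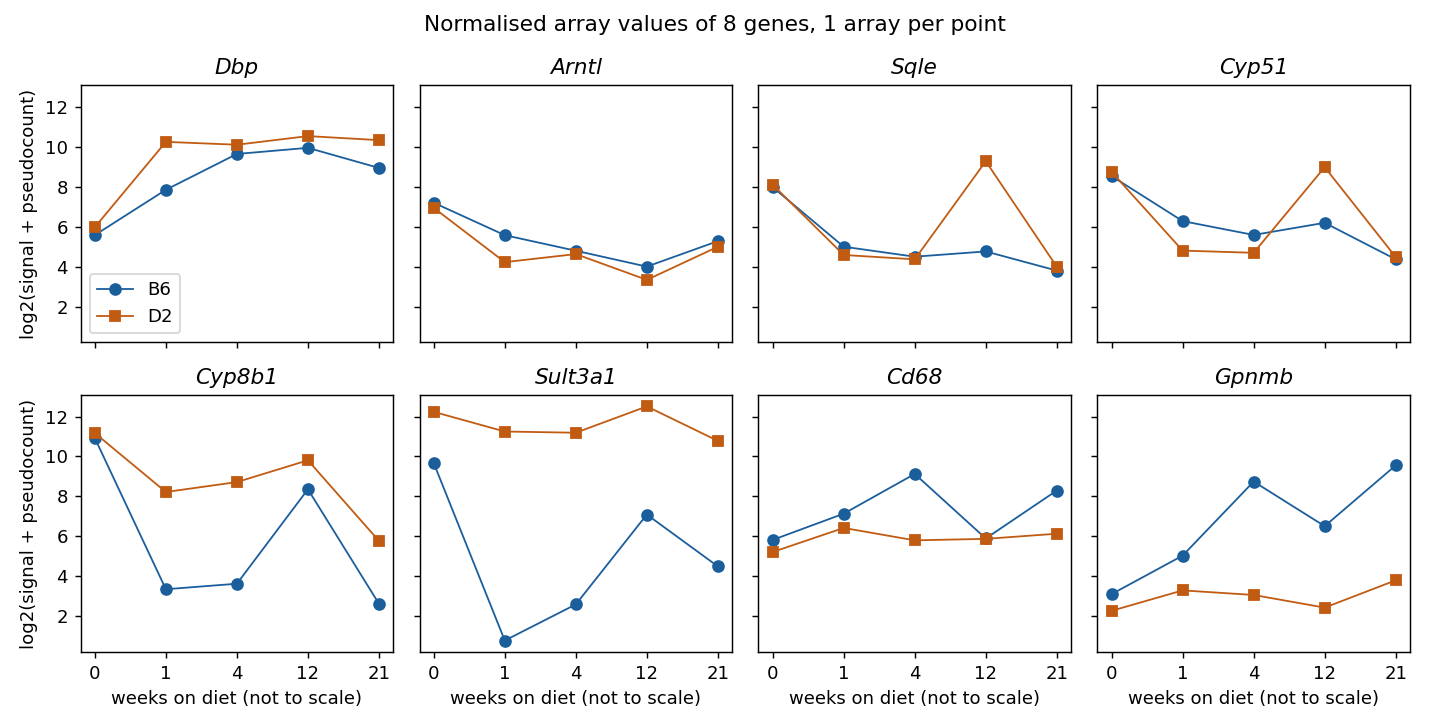
Normalised log2 signal of 8 genes (vertical axis, log2(signal + pseudocount)) against weeks on the diet (horizontal axis, evenly spaced and not to scale), with 1 array per point, B6 as circles and D2 as squares. Dbp was at 5.58 and 5.97 before the diet and at 7.84 or above in every fed array, and Sqle was at 9.27 in D2 at week 12 against 3.99 to 4.58 in the other fed D2 arrays.

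Cholesterol synthesis and uptake genes lay lower in the fed arrays, with a median of −1.02 over 20 genes, all of them negative (camera adjusted p = 5.36e-06, and adjusted p = 0.661 with an estimated correlation). None passed alone, also when adjusted over the list alone (0 of 20), whereas 8 of 20 fell without the D2 week 12 array, with a median of −1.34, and 9 without both week 12 arrays. Cyp51, a demethylase of sterol synthesis, had a change of −2.96 ± 0.98 (adjusted p = 0.165), and Sqle, the squalene epoxidase, of −3.00 ± 1.08 (adjusted p = 0.193). Nsdhl, a further enzyme of the pathway, had −2.20 ± 0.69. In the D2 week 12 array the median of the list was 0.92 above week 0, while it was −1.80, −1.68 and −1.96 at weeks 1, 4 and 21 in D2 and between −0.86 and −1.88 in B6. Targets of the sterol receptor LXR had a median of 0.60 over 13 genes, with 1 rising, Scd1, or 5 over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.57 with an estimated correlation). Abcg5, a sterol efflux transporter gene, had a change of 1.16 ± 0.25 (adjusted p = 0.0612), and Srebf1, a regulator of lipogenesis, of 1.66 ± 0.46 (adjusted p = 0.11). Without the B6 week 0 array, which leaves the change of D2 alone, the LXR median was 0.18 and the call was lost. It was also lost at the authors' own scale (median 1.04, or 0.52 relative to all genes, adjusted p = 0.215). With arrays centred on their median the call was lost as well (0.68, adjusted p = 0.0571). Without the B6 week 4 array the median was 0.36 (adjusted p = 0.0248).

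Genes of the fasting liver lay lower in the fed arrays, where fed means on the diet. Whether the mice fasted before collection is not known here. For these genes and Pdk4, a different feeding state at week 0 therefore cannot be told apart from an effect of the diet. The gluconeogenesis and fasting list had a median of −0.51 with 13 of 14 genes negative, 0 passing over all genes and 3 falling over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.57 with an estimated correlation). Its median was −0.24 at the authors' own scale, or −0.76 relative to all genes, with 1 gene rising and 1 falling. Without the B6 week 0 array, and so in D2 alone, the median was −0.31. Igfbp1, an insulin-repressed binding protein gene, had a change of −1.18 ± 0.36 (adjusted p = 0.133) and the coactivator gene Ppargc1a of −0.80 ± 0.23 (adjusted p = 0.12). After normalisation, medians were also below 0 for 30 fatty acid oxidation genes (−0.19, with Pdk4 falling), 23 drug-metabolising cytochrome P450 genes (−0.14, with Cyp2b10 falling), 16 bile acid synthesis genes (−0.13, 5 falling over the list alone) and 17 genes of the unfolded protein response (−0.23). Their medians were 0.22, 0.16, 0.25 and 0.10 at the authors' own scale, below the shift of all genes. Camera adjusted p-values were 0.0138, 0.00466, 0.0434 and 0.0432, and with an estimated correlation the adjusted p-values were 0.661, 0.57, 0.607 and 0.661. Cyp8b1 of the bile acid list was at 10.92 before the diet and 4.50 ± 2.61 after it in B6, and at 11.17 and 8.13 ± 1.70 in D2 (SD, n = 4 fed arrays, adjusted p = 0.127). Male-biased liver genes had a median of −0.55 over 11 genes, with 3 falling over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.661 with an estimated correlation). At the authors' own scale this median was −0.05, or −0.57 relative to all genes (camera adjusted p = 1.19e-06, and adjusted p = 0.18 with an estimated correlation). After normalisation the call of the male-biased list was lost without B6 week 0, B6 week 21, D2 week 12 or D2 week 21. Without the B6 week 0 array, which leaves the change of D2 alone, the fatty acid oxidation median was 0.10 and the call was lost. Of the 13 lists called for the diet, 11 lost their call without at least 1 array.

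Lists of immune cell genes had positive medians in the fed arrays of both strains together. All 25 macrophage and Kupffer cell markers had a positive change, with a median of 0.79 (camera adjusted p = 0.00104), as did all 13 antigen presentation genes, with a median of 0.71 (camera adjusted p = 0.00259), and 15 of 16 interferon response genes, with a median of 0.53 (camera adjusted p = 0.0274). All 3 lists had an adjusted p of 0.661 with an estimated correlation, and 0 of their genes passed alone, also over the lists alone. In D2 alone the medians were 0.29, 0.53 and 0.07 and none of the 3 was called (camera adjusted p = 0.697, 0.22 and 0.971). At weeks 1, 4, 12 and 21 in D2 they were 0.44, −0.04, −0.06 and 0.44 for macrophage, 0.49, 0.20, 0.82 and 0.54 for antigen presentation and 0.38, −0.25, 0.07 and −0.28 for interferon response genes. Without B6 week 4 antigen presentation was called in D2 (camera adjusted p = 0.00431) with a median of 0.53, against 0.62 in B6. Lgals3, a galectin gene of activated macrophages, had a change of 1.94 ± 0.80 (adjusted p = 0.246), with 3.17 in B6 and 0.71 in D2. Cd74, the MHC class II invariant chain, had a change of 1.44 ± 0.60 (adjusted p = 0.249). The immunoproteasome gene Psmb9 had 1.43 ± 0.46 (adjusted p = 0.15). The macrophage marker Cd68 had 1.31 ± 0.62 (adjusted p = 0.306), the collagen gene Col1a1 1.10 ± 0.97 (adjusted p = 0.581) and the acute phase gene Saa1 0.03 ± 0.90 (adjusted p = 0.988). Over the same arrays the median of 13 hepatocyte markers was −0.07 and that of 6 blood cell markers 0.40. Without the B6 week 0 array all 3 calls were lost, which repeats the result in D2 alone, since B6 then no longer enters the change. At the authors' own scale the 3 lists had camera adjusted p-values of 0.717, 0.181 and 0.717. Their medians there were 1.26, 1.27 and 1.07 (0.74, 0.75 and 0.56 relative to all genes), with 9, 8 and 3 genes rising. Circadian clock genes had a median of 0.67, with 4 of 16 rising and 1 falling, or 7 and 4 over the list alone (camera adjusted p = 0.0274, and adjusted p = 0.613 with an estimated correlation). The clock call was lost without D2 week 0 or D2 week 12 and at the authors' own scale (camera adjusted p = 0.717). At that scale the median was 1.17, or 0.66 relative to all genes, with 10 genes rising and 2 falling. NRF2 and glutathione genes had a median of 0.20 over 19 genes (camera adjusted p = 0.0434, and adjusted p = 0.661 with an estimated correlation). It ranged from 0.10 to 0.39 with 1 array left out, and the call was lost for 5 of 10 arrays (adjusted p up to 0.699) and at the authors' own scale (adjusted p = 0.811; median 0.69, or 0.17 relative to all genes, with 8 genes rising).

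**Figure D3:**
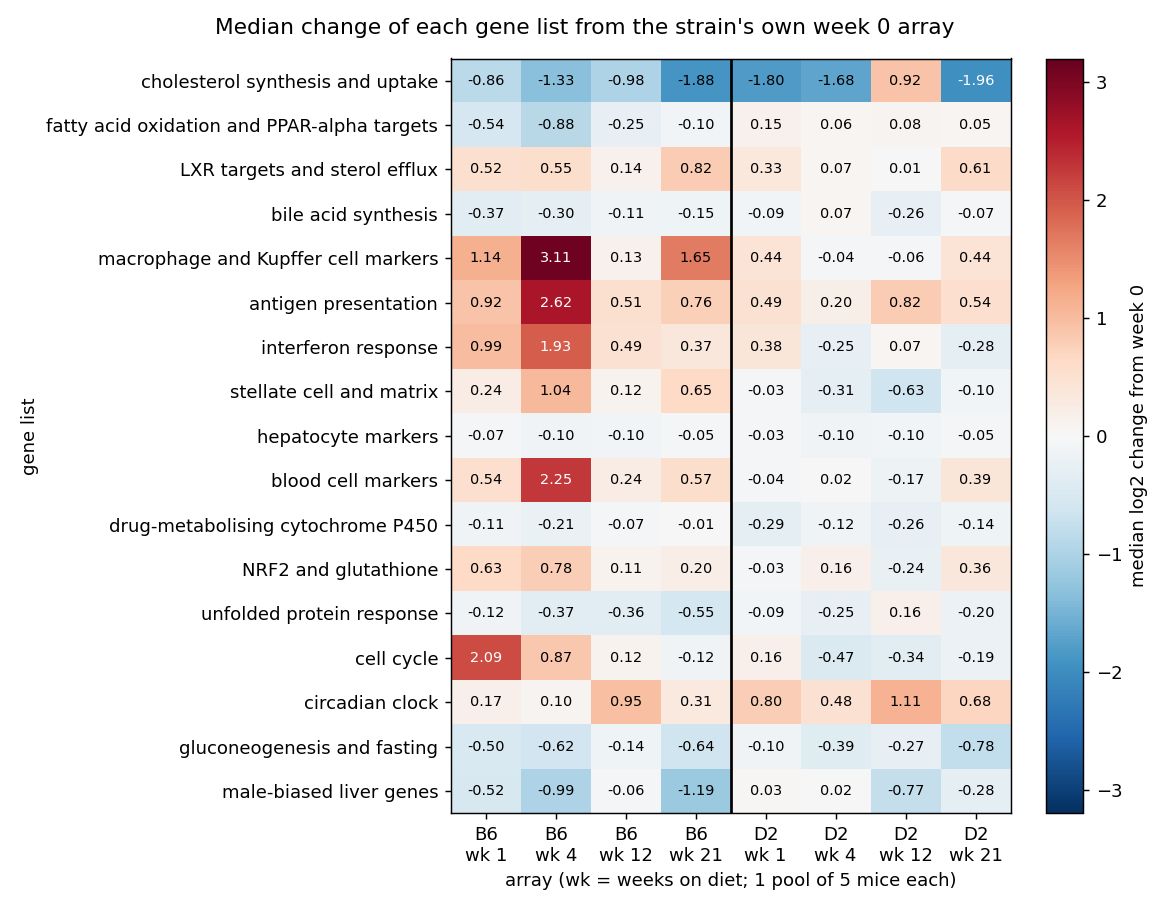
Median log2 change of gene lists (vertical axis) from the week 0 array of the same strain in each of the 8 fed arrays (horizontal axis), as a colour scale with the value in each cell. The macrophage and Kupffer cell list reached 3.11 in B6 at week 4, and the cholesterol list was at 0.92 in D2 at week 12 and below 0 in the other fed arrays.

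Within single strains the response was tested against 1 array before the diet, which was assumed to vary like the fed arrays. In B6, 13 genes passed, 12 rising, among them Mlkl (3.37 ± 0.46, adjusted p = 0.0327), and 1 falling, Avpr1a (−1.59 ± 0.23, adjusted p = 0.044). In D2, 13 genes rose and 0 fell. They included Dbp (4.33 ± 0.60, adjusted p = 0.0349), Scd1 (1.29 ± 0.12, adjusted p = 0.00306) and Clcn5, a chloride transporter gene (3.51 ± 0.25, adjusted p = 0.00133). These examples were chosen after their values were seen. The strains shared 0 of these calls, where independent lists of this length would share 0.0153. The difference between the strains' changes was itself not past the threshold for Mlkl (−1.74 ± 0.65, adjusted p = 0.74), Avpr1a (0.28 ± 0.33, adjusted p = 0.935), Dbp (0.81 ± 0.85, adjusted p = 0.935) or Scd1 (0.78 ± 0.16, adjusted p = 0.377). The counts ranged from 0 to 22 in B6 and from 6 to 21 in D2 when 1 array was left out, and B6 had 0 calls without the D2 array of week 1, 4 or 21 and 1 without its own week 21 array.

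The third comparison asked where the strains' responses to the diet differed. Clcn5 was the 1 gene of 11062 that passed (674 had an unadjusted p under 0.05), with a difference of 3.67 ± 0.36 between the change in D2 and that in B6 (adjusted p = 0.0203). It was at 7.37 before the diet and 7.21 ± 0.08 after it in B6, and at 3.32 and 6.82 ± 0.33 in D2 (SD, n = 4 fed arrays). Its probe set can bind more than 1 transcript, and through another probe set of the gene the difference was −0.11. The call was also lost without any 1 fed array except D2 week 12 (adjusted p up to 0.0948).

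In 5 gene lists the strains' changes lay apart by camera. Macrophage and Kupffer cell markers had smaller changes in D2 than in B6, with a median difference of −1.26 and all 25 genes negative (camera adjusted p = 0.000121), as did 15 of 16 interferon response genes (−0.87, camera adjusted p = 0.000985), 21 of 24 stellate cell and matrix genes (−0.63, camera adjusted p = 0.000727) and 15 of 17 cell cycle genes (−1.02, camera adjusted p = 0.0264). Fatty acid oxidation genes lay the other way, with 28 of 30 positive and a median of 0.52 (camera adjusted p = 1.81e-05). Each of the 5 had an adjusted p of 0.925 with an estimated correlation, and 0 of their genes passed, also adjusted over the lists alone. Itgax, an integrin gene of myeloid cells, had a difference of −2.53 ± 1.28, the interferon-induced Mx1 of −2.57 ± 0.71 and the collagen gene Col3a1 of −1.92 ± 0.97. Hadha, a subunit of the mitochondrial trifunctional protein, had 0.69 ± 0.26, and Decr2, a peroxisomal reductase gene, 1.01 ± 0.33. Cyp7a1 was at 9.67 before the diet and 7.83 ± 1.56 after it in B6, and at 9.14 and 10.02 ± 0.33 in D2 (adjusted p = 0.857). Medians of blood cell (−0.86) and lymphocyte markers (−0.79) had the same sign and were not called (camera adjusted p = 0.228 and 0.688). Without B6 week 4 the macrophage median was −0.79 and the fatty acid oxidation median 0.34. The interferon median of D2 minus B6 was 0.85 at week 0 and 0.10, −1.14, 0.50 and 0.32 at the fed weeks, and the interaction median was −0.60 without the B6 week 4 array. The cell cycle call was lost without B6 week 1 (median −0.55, adjusted p = 0.148) or D2 week 4, and 9 lists were called without B6 week 12.

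The fourth comparison asked whether transcripts changed in level from 1 to 21 weeks on the diet. In limma, 0 of 11062 genes had a slope past the threshold over the 8 fed arrays, with a smallest adjusted p of 0.841 and 523 genes at an unadjusted p under 0.05. The smallest p was that of Adgrg2, an adhesion receptor gene, with a slope of 0.42 ± 0.06 per doubling of weeks. Cell cycle genes had negative slopes, with a median of −0.31 and all 17 genes negative, 9 of them falling adjusted over the list alone (camera adjusted p = 7e-15, and adjusted p = 0.94 with an estimated correlation). The median change from week 0 at weeks 1, 4, 12 and 21 was 2.09, 0.87, 0.12 and −0.12 in B6 and 0.16, −0.47, −0.34 and −0.19 in D2. Examples are the mitotic genes Cdc20 (−0.45 ± 0.11, adjusted p = 0.972) and Aurka (−0.41 ± 0.09, adjusted p = 0.972). All 16 interferon response genes had a negative slope, with a median of −0.15 (camera adjusted p = 8.26e-08, and adjusted p = 0.94 with an estimated correlation), as in Ifit1 (−0.26 ± 0.11). Medians were −0.13 for male-biased liver genes, 0.12 for female-biased liver genes, 0.04 for fatty acid oxidation genes and −0.05 for NRF2 and glutathione genes (camera adjusted p = 0.000745, 0.0373, 0.000493 and 0.0311). These 4 lists too had an adjusted p of 0.94 with an estimated correlation. The cell cycle and interferon calls held whichever fed array was left out, though the cell cycle slope was −0.18 without B6 week 1. The other 4 were lost without B6 week 21 (adjusted p = 0.0879, 0.0847, 0.417 and 0.252). With 1 array left out their medians ranged from −0.15 to −0.10 (male-biased) and from 0.06 to 0.22 (female-biased). For fatty acid oxidation the range was −0.0014 to 0.09, and for NRF2 and glutathione −0.12 to −0.03. The NRF2 and female-biased calls were each lost for 5 of the 8 fed arrays left out (adjusted p up to 0.982 and 0.155), the week 0 arrays not being part of this fit. With B6 week 1 left out 10 lists were called, and with D2 week 21 left out 11.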

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

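The tests on the D2 week 12 array and on the clock genes were chosen after the result was seen, while the other tests here were planned. A sample was examined where it lay far from the other 4 arrays of its strain, which chance does for about 1 in 20 groups. Of 158 groups of 5 arrays for 79 named genes, 21 had such an array, and in 18 of them it was the week 0 array, the only one without the diet. Many of these genes were named because they were called against week 0, so their number cannot be set against chance. In D2 at week 0 these were Dbp (5.97), Nr1d1 (4.34), Per3 (4.46), Mlkl (4.38), Scd1 (11.23), Clcn5 (3.32), Psmb9 (6.46), Hadha (10.23) and Nudt7 (10.21) below the fed arrays, and Pdk4 (8.72), Ccng2 (8.57), Htr1b (6.38), Nlrp12 (5.07) and Klrd1 (3.77) above them. In B6 at week 0 they were Abcg5 (9.02) and Scd1 (12.26) below and Avpr1a (7.83) and Sqle (7.98) above. The others were Cdc20 (6.99) and Aurka (5.87), highest in B6 at week 1, and Corin (3.24), highest in B6 at week 21. Among 50 groups for gene lists, 2 had such an array. Blood cell markers stood at 1.66 in B6 at week 4 and fatty acid oxidation genes at 0.19 in D2 at week 1, as list values centred across arrays.

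By a test of the difference itself, the response to the diet differed between the strains in Clcn5 (3.67, adjusted p = 0.0203). Another probe set of Clcn5 gave −0.11, the difference rests on the D2 week 0 array, and the call was kept for 1 of 8 fed arrays left out. It also differed in the camera test of fatty acid oxidation genes (0.52), macrophage and Kupffer cell markers (−1.26), interferon response genes (−0.87), stellate cell and matrix genes (−0.63) and cell cycle genes (−1.02). With an estimated correlation none of these lists was called (adjusted p = 0.925).

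The 883 genes that differed between the strains were set against other divisions of the arrays. Of 100 splits of the 10 arrays into 5 and 5, only 1, the real one, called as many genes, and the highest count in another split was 4. Only 16 splits part the arrays of every week, as the week block asks. Among these the real one alone called as many genes, and the highest other count was 0. This test cannot exclude a random division, since 1 in 16 is its lowest result and other splits put the strain difference into the spread. For the diet, 1 of 25 choices of a B6 and a D2 array as the reference pair called 72 genes, the week 0 pair, and the highest count in any other pair was 0. Every other choice left at least 1 week 0 array among the fed arrays, which puts the difference from week 0 into the spread. Low counts were therefore likely in advance, and 1 in 25 is the lowest result, so no conclusion is drawn from this test.

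Lower signals in D2 could come from probes that mismatch D2 sequence, as the arrays were designed on a reference close to B6. Of 203 genes called lower in D2 that had a second probe set, 80.8% had it in the same direction (Wilson interval 74.8 to 85.6), against 88.0% of 183 genes called higher and 68.1% of uncalled genes. The value met the limit set in advance, 80% or more, which would have argued against mismatches. The interval was not part of that rule as written, and it reaches below the limit. A true difference between the strains and probe mismatches therefore cannot be told apart for genes called lower in D2.

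Cholesterol synthesis genes were high in the D2 week 12 array, at a median of 0.92 above week 0, while the other fed D2 arrays were at −1.80, −1.68 and −1.96. Quantile normalisation is argued against, since in the deposited values the median was 1.51 at week 12 and −1.49, −1.37 and −1.43 at the others, and 1.00 at week 12 relative to all genes, a value that no single factor per array can alter. So is a pool wholly of B6 RNA, since all 6 strain label genes lay closer to the other D2 arrays. This measure cannot exclude a share of B6 RNA. In B6 week 0, B6 week 12 and D2 week 0, 5 of the 6 genes lay closer to their own strain. Of 100 genes chosen for the diet response in the B6 arrays alone, 70% lay on the fed side of D2 week 0 in this array (Wilson interval 60.4 to 78.1), against 83%, 80% and 79% in the other fed D2 arrays. The value for week 12 met the limit first set, 70%, which would have argued against an unfed pool. After it was seen, the limit was tightened to an interval lying wholly above 70%, and an earlier version of the test on other genes had been dropped because their choice biased it. An unfed pool in place of the fed one therefore cannot be told apart from a change at this week, as genes are not independent and there is 1 array. No biological explanation was tested.

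Clock genes stood apart between the week 0 and fed arrays. Genes that peak with Dbp and genes that peak with Arntl moved in opposite directions from week 0 in 8 of 8 fed arrays, with medians from 0.62 to 1.96 for the first and from −1.12 to −2.37 for the second. All fed arrays of a strain share its 1 week 0 array, so the 8 are not independent. Dbp and Arntl had already been called in opposite directions. Quantile normalisation is argued against, since in the deposited values Dbp still rose (4.47, adjusted p = 0.000767) and Arntl still fell (−1.93, adjusted p = 0.0109), and 0 of the clock genes called for the diet turned relative to all genes. Single factors per array move all genes alike, so this was 1 comparison. A different hour of collection at week 0 cannot be told apart from an effect of the diet, because the labels give no hour.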

How the results depend on the processing

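The alternatives with values as deposited, with values centred on the tested genes, without both week 12 arrays, and without B6 week 4 and D2 week 12, and centring on the median for the gene lists, were chosen after the data were seen. Of the values of named genes under the alternatives, 2270 stayed on the same side of the threshold for strain, 349 became weaker and 16 stronger. These counts were 2832, 103 and 84 for the diet, and without stronger ones 2427 and 9 for the interaction and 3171 and 0 for the trend. A turn in direction was counted only where a value passed in the main or the alternative fit. The counts therefore do not show that values that did not pass, which are all those of the trend, kept their direction. For the gene lists called in the main fit, 132 values kept call and direction and 28 became weaker for strain. These counts were 192 and 68 for the diet, 77 and 13 for the interaction, and 88 and 32 for the trend. With the pseudocount at the 25th percentile, 0 genes passed in B6 and 6 in D2. With a floor, 23 passed in D2, and with median centring 313 passed for the diet. Without a filter 8 passed in D2, and with probe sets above the 75th percentile 0 passed in B6 and 2 in D2. With every probe set tested, 1538 passed for strain, 140 for the diet, 33 in B6, 120 in D2 and 3 for the interaction, out of 22519. The interaction had 0 genes with the mean of each gene's probe sets, without probe sets that bind several transcripts (where Clcn5 reversed to −0.11), without a variance trend, and with a slope on log2(week + 1). Without a variance trend, 33 passed in B6 and 38 in D2. Without week 21, 14 passed for the diet. With the B6 arrays alone 0 passed in B6, and with the D2 arrays alone 1 gene passed for the trend. With an estimated correlation, and with the directional test of fry, 0 lists were called in the strain, diet, interaction and trend comparisons, while fry's test for changes in either direction called 15, 7, 1 and 0. As deposited, 4990 genes passed for the diet, 1946 in B6 and 45 in D2, and with these values centred on the tested genes 0 passed in B6 and 5 in D2. Without both week 12 arrays 427 genes passed for strain, 22 in B6 and 23 in D2, and 10 lists for the interaction. Without B6 week 4 and D2 week 12, 214 passed for strain and 3 in B6. The week block pairs the strains' pools of a week, and without this block 774 genes passed for strain. Leaving out 1 array gave 386 to 715 genes for strain, 14 to 95 for the diet, 0 to 22 in B6, 6 to 21 in D2, 0 to 1 for the interaction and 0 to 0 for the trend, and 6 to 10, 4 to 15, 4 to 9 and 5 to 11 lists for strain, diet, interaction and trend. The response of a strain could not be fitted without its week 0 array, and quantile normalisation, planned as an alternative, had become the rule. Leaving out arrays also lowers the degrees of freedom; for the other alternatives the cause was not tested. Signals near background limit what the arrays show for weakly expressed genes.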

Other observations

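The values in this part were picked out after the results were seen. In B6 the array of week 4 stood highest in markers of immune cells, and in blood cell markers (median change 2.25), lymphocyte markers (1.06) and stellate cell and matrix genes (1.04). Its 3' to 5' ratio of actin was 1.78, the lowest of the 10 arrays, while that of Gapdh was 0.73, the highest of the 10. Compared with the B6 week 0 array, the median change at weeks 1, 4, 12 and 21 was 1.14, 3.11, 0.13 and 1.65 for macrophage and Kupffer cell markers, 0.92, 2.62, 0.51 and 0.76 for antigen presentation genes, and 0.99, 1.93, 0.49 and 0.37 for interferon response genes. The macrophage values in D2 were 0.44, −0.04, −0.06 and 0.44. Saa1, an acute phase gene, differed from week 0 by 1.93, 3.55 and −0.34 in B6 at weeks 1, 4 and 12 and stood at 10.90 at week 21, and it differed by −1.25, −2.16, −2.37 and −0.99 at the 4 fed weeks in D2. The neutrophil gene S100a8 was at 3.32, 4.41, 8.16, 4.16 and 5.38 in B6 at weeks 0, 1, 4, 12 and 21, and Lcn2, an iron-binding protein gene of inflammation, at 8.55, 9.27, 12.15, 6.29 and 10.17. Gpnmb, a gene of lipid-laden macrophages, was at 3.11, 5.04, 8.74, 6.51 and 9.56 in B6.

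Cell cycle genes were highest in B6 at week 1, with a median change of 2.09 from week 0, against 0.87, 0.12 and −0.12 at weeks 4, 12 and 21. The replication gene Mcm5 was at 3.38 at week 0 and 8.10 at week 1 in B6, and at 4.10 and 5.09 in D2. Among single genes, Cyp8b1 was at 10.92, 3.36, 3.63, 8.36 and 2.63 in B6 over the weeks and at 11.17, 8.22, 8.72, 9.81 and 5.78 in D2. Cyp7a1 was at 9.67, 5.98, 7.46, 9.73 and 8.15 in B6. Sult3a1 was at 9.67, 0.79, 2.60, 7.09 and 4.50 in B6, and the organic anion transporter gene Slco1a1 at 8.70, 6.86, 1.39, 6.28 and 3.47. Each of these values is from 1 array.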
